A study of Homo sapiens with 9 samples.

How the data were processed

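RNA from SUM149 cells, an established human triple-negative breast cancer line, was measured on 9 whole-transcript Affymetrix arrays. Per the labels, cells received a negative control gapmer, gapmer 3 or gapmer 4 against the long non-coding RNA NRAD1 at 15 nM for 48 h, with 3 arrays per group, and total RNA was labelled with the WT PLUS chemistry and biotin. The deposited values are log2 intensities, as judged from their range of 1.10 to 13.8. How the authors summarised the probes, corrected the background and normalised between arrays, and the genome build, are not given in the sources used here. The 9 array medians lie between 5.30 and 5.37, so the deposited values were on one scale between arrays and were used without rescaling. The table holds 52037 probes, and 3 or more arrays share exactly the same value in 26.5% of them.

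Of 468333 cells, 61 were blank and 68 were at or near 0 beside ordinary values of the same probe on other arrays. These 129 cells (0.0275%) were treated as missing. Probes took their names from the platform's probe table, matched to a RefSeq gene table by Entrez identifier: 16025 probes (30.8%) carried 1 symbol, for 14861 genes, and 36012 probes carried none here. Probes whose mean over all arrays was under 4.04, the 25th percentile, were left out. Where several probes of a gene passed, the probe with the highest mean was kept, as for 600 genes. This left 13241 genes. Coordinates are not printed. The gene table (assembly GRCh38.p14) served only for names, neighbours and gene lengths.

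One linear model with the 3 groups was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, using moderated variances with an intensity trend (6 residual and 4.23 prior degrees of freedom). The comparisons were each gapmer with the control, the mean of both gapmers with the control, and gapmer 4 with gapmer 3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene is limma's. Values after ± are standard errors of the fitted difference unless marked SD, with n = 3 arrays per group. For NRAD1 alone, a two-sided exact permutation test was added in R. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

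There were 38 gene lists of pathways, cell states and cell-type markers, fixed before the data were examined, of which 35 had the 5 measured members needed for a test. They hold 886 symbols, of which 538 were named on the array. Lists were tested against all other genes with camera in limma at its preset correlation of 0.01, adjusted over the 35 lists, and again with a correlation estimated from the arrays. The fry test was also run. Its p asks whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares a list with other genes. Counts "adjusted over the list alone" correct for the members of that list only.

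Named genes were chosen by a rule fixed before the data were examined. It takes NRAD1 and genes near it, the 6 largest called rises and falls for each gapmer, the 12 largest each way among genes called the same way by both (ranked by the smaller of the 2 changes), the 5 largest differences each way between gapmers, and up to 4 members per described list by mean change. Identifiers such as LOC entries, microRNAs and pseudogenes were not ranked. They account for 41 called genes with gapmer 3, 50 with gapmer 4, 77 between gapmers and 8 of those called the same way by both. STARD4, SNAI2, LOXL2, KRT5, KRT15, SPRR2A, FBN1, MMP14, CD44, ISG15, ICAM1, FASN and SCD fall outside the rule and were chosen after their values were seen.

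Replicate numbers were checked for pairing with the deposited values. After subtracting group means, arrays of the same number in different groups correlated at r from 0.127 to 0.335 across genes, and arrays of different numbers from -0.305 to 0.185. For 7 of 9 arrays the best partner in both other groups was the array of the same number, so a fit with replicate number as a block was run as an alternative. Its values stand beside a described gene or list where they change its call, and beside a total count that they move by over 1.5 times. Counts of list members come from the main fit unless the block is named.

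Because both comparisons with the control use the same 3 control arrays, the overlap of the gapmers was set against 100 simulations with no true change and a shared control group. The model was tested on simulated data of 13241 genes in which 100 genes changed by 0.5 and 100 by 1 on the log2 scale with each gapmer. It recovered 78% and 99% of these with gapmer 3, 73% and 99% with gapmer 4, and 88% and 99% for the mean. False calls numbered 13, 9 and 14, and there were 0 calls between the gapmers.

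Alternatives were no filter and a stricter filter on dim probes, a mean over a gene's probes, quantile normalization, median centring, a variance prior without trend, array weights, only the 6 arrays compared, the replicate block, fold-change minimums, the estimated correlation, and leaving out each array in turn. Leaving out the 3 arrays numbered 1 together and keeping only genes with at most 2 arrays at one value were added after seeing the data. Arrays carry no counts, so their number limits the precision. Probes without a name were tested separately and are given only as counts. Array intensities before summarization were not used here, and no search with the gapmers' sequences was made.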

Results

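The 9 arrays profiled SUM149 cells, a triple-negative breast cancer line grown in culture, after exposure to gapmers. Gapmers are short antisense oligonucleotides with a DNA core that lets RNase H cleave the RNA they bind. NRAD1 is a long non-coding RNA, and the series compares 3 arrays of cells given a negative control gapmer with 3 given gapmer 3 and 3 given gapmer 4, all at 15 nM for 48 h. Array medians lay between 5.30 and 5.37 on the log2 scale. Arrays of the same group correlated at 0.986 to 0.990 across probes and arrays of different groups at 0.981 to 0.989. The main axis of variation, with 45.1% of the variance, set gapmer 4 apart (scores from 19.3 to 25.6) from control and gapmer 3 arrays (-12.8 to -8.39). The next axis, with 20.9%, set control arrays (13.1 to 14.6) apart from gapmer 3 arrays (-14.3 to -12.0). The labels do not say whether replicates are separate cultures, so all p-values measure only the spread between these samples.

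The question for the target itself was whether NRAD1 RNA was lower after each gapmer. Its single probe (16774436) read 4.67 ± 0.26 (SD, n = 3) in control arrays, 4.33 ± 0.24 with gapmer 3 and 4.44 ± 0.05 with gapmer 4. The fitted differences were -0.34 ± 0.146 with gapmer 3 (21.2% lower, 95% interval -0.67 to -0.02 on the log2 scale, adjusted p = 0.224) and -0.23 ± 0.146 with gapmer 4 (14.9% lower, -0.56 to 0.09, adjusted p = 0.379). Neither passed at the adjusted p, while limma's unadjusted p was 0.0404 with gapmer 3 and 0.143 with gapmer 4. Two-sided exact permutation tests gave p = 0.2 and p = 0.3, where 3 arrays against 3 allow no p under 0.1. With array weights the differences were -0.18 (adjusted p = 0.402) and -0.15 (0.490), and without control replicate 1 they were -0.20 (0.524) and -0.09 (0.771). Without gapmer 3 replicate 1, gapmer 3 read -0.21 (0.497). For the mean of both gapmers the difference was -0.29 ± 0.127 (95% interval -0.569 to -0.006). Its limma p was 0.0461 unadjusted and 0.208 adjusted. The probe sat at the 32.5th percentile of brightness and 4 of its 9 arrays read exactly 4.467.

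Of 5 measured genes around NRAD1, 1 was called with gapmer 4 and 0 with gapmer 3. Adjusted over the list alone, 2 rose with gapmer 3, and 1 rose and 1 fell with gapmer 4. In RefSeq on GRCh38.p14, ENOX1, CCDC122 and LACC1 lie on one side and SERP2 on the other. ENOX1, which encodes a cell-surface oxidase, fell by 0.44 ± 0.123 with gapmer 4 (adjusted p = 0.0392). That call was lost without any 1 of 6 arrays (all 3 controls, gapmer 3 replicate 2, gapmer 4 replicates 2 and 3), at adjusted p from 0.0530 to 0.130. Of the 5 neighbours measured, limma called 0 with gapmer 3 (2 at an unadjusted p under 0.05, 2 with the replicate block): CCDC122 read 0.50 ± 0.160 (adjusted p = 0.0918; 0.0301 with the block), LACC1 0.32 ± 0.107 (0.111; 0.0085 with the block) and SERP2 0.25 ± 0.126 (0.312). LACC1 was also at 0.32 with gapmer 4 (adjusted p = 0.0828; 0.0054 with the block). CCDC122 differed between gapmers by -0.71 ± 0.160 (adjusted p = 0.0122).

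**Figure D1:**
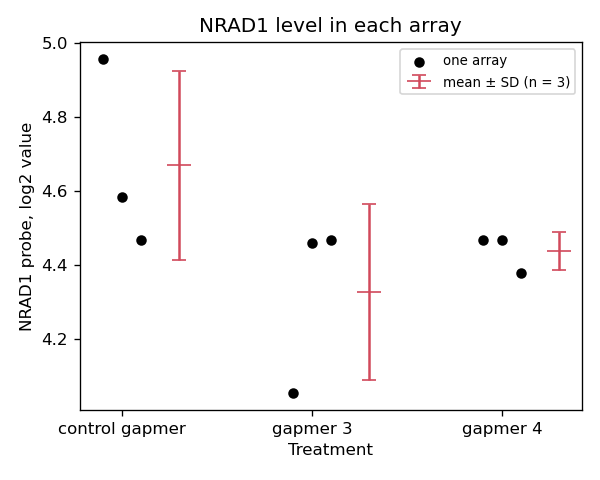
Deposited log2 intensity of the NRAD1 probe on each array (points) with the group mean and SD. Control arrays average 4.67, gapmer 3 arrays 4.33 and gapmer 4 arrays 4.44, and 4 arrays share the value 4.467.

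Gapmer 3 was compared with the control to ask what else changed after it. Among the genes ranked, the strongest rise was KRT10, a keratin of differentiating epidermis, up 5.92-fold (log2 2.57 ± 0.093, n = 3 per group, adjusted p = 3.29e-07). GPR89A and GPR89B, near-identical genes for a Golgi anion channel whose probes may not be told apart, rose by 2.06 and 1.93. DDX60 and IFI44, both induced by interferon, rose by 1.66 ± 0.210 and 1.52 ± 0.196, and CGGBP1, a binder of CGG repeats, by 1.48 ± 0.092. The deepest fall among them was JAK1, a kinase of interferon and other cytokine receptors, which fell by 1.97 ± 0.078 (adjusted p = 4.83e-07). TMEM50B fell by 1.85 (by 1.18 as a mean over its probes), MARF1, a regulator of RNA stability, by 1.79, NOP2, an rRNA methyltransferase, by 1.70, the nucleoporin NUP205 by 1.65 and the peptidase TPP2 by 1.62. TBP, the TATA-binding protein often used as a reference gene, fell by 1.54 ± 0.120 (adjusted p = 4.22e-05). RARRES1, a gene induced by retinoic acid, fell by 0.98 ± 0.127, UHRF1, a cofactor of DNA methylation upkeep, by 1.02 ± 0.159, and the long non-coding RNA LINC00707 by 1.62 ± 0.204.

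In all, 1090 of 13241 genes were called with gapmer 3, of which 424 rose and 666 fell. At least 2-fold changes numbered 30 rises and 60 falls. The replicate block called 1801 genes, while 677 were called without control replicate 3 and 719 without gapmer 3 replicate 2.

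Of the 35 lists tested, 6 were called with gapmer 3, 4 up and 2 down, and none of the 6 held with an estimated correlation. Interferon response genes rose for 6 of 21 members and fell for 0 (8 and 0 adjusted over the list alone), with a mean of 0.41 and a median of 0.13. The list's adjusted p was 0.0076, and adjusted p = 0.800 with an estimated correlation. Besides DDX60 and IFI44, the antiviral genes IFIT2 (1.20 ± 0.211), IFIT1 (1.18 ± 0.272) and IFIT3 (0.87 ± 0.218) were among them. The calls of IFIT1 and IFIT3 were each lost without control replicate 1, control replicate 3, gapmer 3 replicate 1 or gapmer 3 replicate 3, and that of IFIT3 also without control replicate 2 or gapmer 4 replicate 2. Their adjusted p then lay between 0.0757 and 0.0825 for IFIT1 and between 0.0542 and 0.121 for IFIT3.

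Genes of basal and squamous cells rose for 5 of 17 members and fell for 1, with the same counts adjusted over the list alone. The 5 were KRT10, the desmosomal cadherin DSG3 (1.03 ± 0.124) and the keratins KRT5 (0.71), KRT16 (0.64) and KRT15 (0.57). SPRR2A, a precursor of the cornified envelope, fell by 0.49. The list mean was 0.35 at adjusted p = 0.0084, and adjusted p = 0.800 with an estimated correlation. KRT15 lost its call without gapmer 3 replicate 2 or 3 (adjusted p 0.0562 to 0.0819), and SPRR2A without control replicate 2 or 3 (0.0513 to 0.0571). Mesenchymal genes rose for 3 of 16 and fell for 1, or 7 and 1 adjusted over the list alone, and the replicate block called 7. SNAI2, a repressor of epithelial genes, rose by 0.94 ± 0.097, the intermediate filament VIM by 0.50 and fibronectin (FN1) by 0.39. The collagen crosslinking enzyme LOXL2 fell by 0.82. The mean was 0.19 at adjusted p = 0.0141, and adjusted p = 0.464 with an estimated correlation.

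The other 3 lists called with gapmer 3 each depended on single arrays. Cholesterol synthesis genes fell for 2 of 16, HMGCS1 by 0.57 ± 0.153 and SQLE by 0.46 ± 0.082, both enzymes of the pathway. STARD4, a cholesterol carrier, rose by 0.31. Adjusted over the list alone, 1 rose and 4 fell, and the replicate block called 8 of the 16. The mean was -0.19 at adjusted p = 0.0411, and adjusted p = 0.800 with an estimated correlation. Genes of repair by homologous recombination fell for 2 of 14 (2 adjusted over the list alone), BARD1, the partner of BRCA1, by 1.42 ± 0.164 and XRCC3 by 0.55 ± 0.132. The replicate block called 6 of the 14 members. Their mean was -0.26 at adjusted p = 0.0446, and adjusted p = 0.800 with an estimated correlation. Metallothioneins, which bind metal ions, rose for 1 of 5, MT1X by 0.58 (1 adjusted over the list alone), with a mean of 0.25 at adjusted p = 0.0446, and adjusted p = 0.800 with an estimated correlation. The cholesterol call was lost without control replicate 1 (adjusted p = 0.132), gapmer 3 replicate 2 (0.0971) or gapmer 3 replicate 3 (0.110), and with a stricter filter on dim probes (0.0790). The repair call was lost without control replicate 1 (0.327), gapmer 3 replicate 2 (0.153), gapmer 3 replicate 3 (0.0910) or gapmer 4 replicate 3 (0.0548). It was also lost with quantile normalization (0.0594), the stricter filter (0.0916), only the 6 arrays compared (0.0548) and a variance prior without trend (0.0512). Without control replicate 1 the mean was -0.14. The metallothionein call was lost without control replicate 3 (0.122), gapmer 3 replicate 1 (0.143), gapmer 3 replicate 2 (0.0824) or gapmer 4 replicate 3 (0.0548). It was also lost with quantile normalization (0.0528), a prior without trend (0.0595) and no filter on dim probes (0.160), where the mean was 0.09. Among single genes, HMGCS1 lost its call without any 1 of 7 arrays, all but gapmer 3 replicate 1 and gapmer 4 replicate 2 (adjusted p 0.0514 to 0.160). STARD4 lost it without any array but control replicate 1 (0.0579 to 0.133), and XRCC3 without control replicates 1 or 2 or gapmer 3 replicates 2 or 3 (0.0826 to 0.112).

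The replicate block called 9 lists with gapmer 3, the same 6 and 3 more. MAP kinase genes had a mean of -0.12 (adjusted p = 0.0511; 0.0093 with the block), and adjusted p = 0.800 with an estimated correlation. Of 19 members, 1 rose and 3 fell (2 and 4 adjusted over the list alone), and the block called 9. Genes of G2 and M phase had a mean of 0.08 (0.105; 0.019 with the block), and adjusted p = 0.816 with an estimated correlation. Stress response genes downstream of ATF4 had a mean of 0.12 (0.126; 0.0472 with the block), and adjusted p = 0.800 with an estimated correlation.

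Gapmer 4 was compared with the control in the same way. Its 6 largest rises among ranked genes were all genes that interferon induces: IFIT2, up 11.1-fold (log2 3.47 ± 0.211, n = 3 per group, adjusted p = 2.35e-06), IFIT1 (3.26 ± 0.272), IFIT3 (3.18 ± 0.218), IFI44 (2.94 ± 0.196), the ubiquitin ligase HERC6 (2.75 ± 0.210) and the RNA sensor IFIH1 (2.55 ± 0.133). The deepest fall among ranked genes was ERBIN, an ERBB2-binding scaffold, down 10.2-fold (it fell by 3.35 ± 0.136, adjusted p = 2.06e-07). The desmosomal cadherin DSC3 fell by 2.54, KDSR, an enzyme of ceramide synthesis, by 2.46 and the splicing regulator MBNL1 by 2.46 (by 1.16 as a mean over its probes). ANKRD36B fell by 2.35 and PATJ, a tight-junction scaffold, by 2.32. TEAD1, the transcription factor partner of YAP, fell by 1.74 ± 0.083, NASP, a histone chaperone, by 1.61 ± 0.095, and GRHL2, which maintains epithelial junctions, was 2.83-fold lower. In all, 1778 genes were called, of which 772 rose and 1006 fell, with 80 rises and 170 falls of at least 2-fold. Falls made up 56.6% of these calls and 63.5% after median centring of the arrays, so the split between rises and falls depends on scaling.

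Of the 35 lists, 6 were called with gapmer 4, 4 up and 2 down, and none held with an estimated correlation. Interferon response genes rose for 20 of 21 members and fell for 0, with the same counts adjusted over the list alone. ISG15, an interferon-induced ubiquitin-like protein, rose by 1.24 ± 0.160. The list mean was 1.79 and its median 1.89, at adjusted p = 1.23e-22, and adjusted p = 0.170 with an estimated correlation. NF-kB and inflammatory genes rose for 7 of 16 and fell for 0 (12 and 0 adjusted over the list alone, 12 called with the replicate block). They included the chemokines CXCL8 (1.67 ± 0.137) and CCL20 (1.20 ± 0.139) and the prostaglandin synthase PTGS2 (1.61 ± 0.076). The cytokine IL24 read 1.27 ± 0.431 (adjusted p = 0.0857; 2.52e-04 with the replicate block). The list mean was 0.56 at adjusted p = 1.77e-06, and adjusted p = 0.0957 with an estimated correlation.

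Genes downstream of MAP kinase signalling rose for 10 of 19 and fell for 1 with gapmer 4 (14 and 1 adjusted over the list alone). JUN, an AP-1 subunit, rose by 1.07 ± 0.104, and the ERK phosphatases DUSP6 and DUSP5 rose by 1.06 ± 0.092 and 0.79 ± 0.193 (0.46 for DUSP5 as a mean over its probes). ETV4, a transcription factor that ERK signalling induces, fell by 0.69 ± 0.154. DUSP5 lost its call without control replicate 2, control replicate 3, gapmer 4 replicate 1 or gapmer 4 replicate 3 (adjusted p 0.0578 to 0.0833), and ETV4 without gapmer 4 replicate 2 (0.0569). The list mean was 0.36 at adjusted p = 1.02e-04, and adjusted p = 0.383 with an estimated correlation. Mesenchymal genes rose for 5 of 16 and fell for 1 (6 and 2 adjusted over the list alone). TNC, a matrix glycoprotein, rose by 1.69 ± 0.245, VIM by 1.63 ± 0.088, FN1 by 1.00 ± 0.070, the receptor kinase AXL by 0.81 ± 0.101 and the microfibril gene FBN1 by 0.57. The membrane protease MMP14 fell by 0.37, a call lost without any 1 of the 3 controls, gapmer 3 replicate 2 or gapmer 4 replicates 2 or 3 (adjusted p 0.0714 to 0.146). The list mean was 0.36 at adjusted p = 0.0184, and adjusted p = 0.170 with an estimated correlation. In a fit of only the 6 arrays compared, the list's adjusted p was 0.0608.

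The 2 lists called down with gapmer 4 were lists of lipid genes. Fatty acid metabolism genes fell for 10 of 20 and rose for 1 (13 and 2 adjusted over the list alone), with a mean of -0.23 at adjusted p = 7.22e-05, and adjusted p = 0.0957 with an estimated correlation. ACSS2, which makes acetyl-CoA from acetate, fell by 1.30 ± 0.093, ACACA, which commits acetyl-CoA to fatty acid synthesis, by 0.63 ± 0.053 and the desaturase SCD by 0.22 ± 0.035. FASN, the fatty acid synthase, fell by 0.41 ± 0.112, a call lost without control replicate 1 or 2, gapmer 3 replicate 2 or gapmer 4 replicate 2 or 3 (adjusted p 0.0583 to 0.134). PLIN2, which coats lipid droplets, rose by 1.18 ± 0.102. Cholesterol synthesis genes fell for 5 of 16 and rose for 1 (10 and 1 adjusted over the list alone), with a mean of -0.29 at adjusted p = 1.09e-04, and adjusted p = 0.603 with an estimated correlation. The replicate block called 11 of the 16. SREBF2, the regulator of sterol synthesis, fell by 0.66 ± 0.086 and SQLE by 0.40 ± 0.082. With gapmer 3 the fatty acid list was not called (mean 0.01, adjusted p = 0.805), but its members changed both ways. There 3 of 20 rose and 5 fell (3 and 6 adjusted over the list alone).

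**Figure D2:**
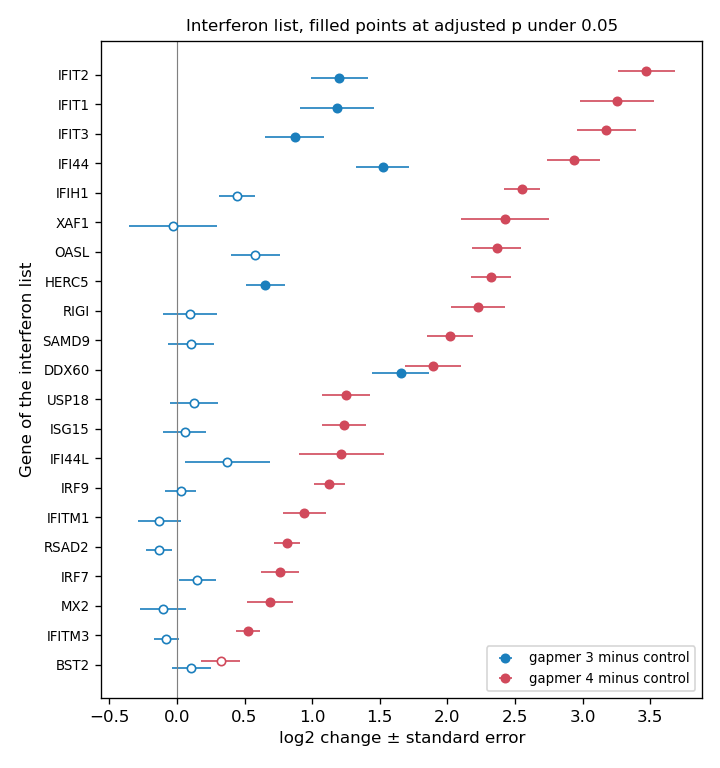
Log2 change from control of each measured interferon response gene with gapmer 3 and gapmer 4, with standard errors. With gapmer 4, 20 of 21 genes rose, led by IFIT2 at 3.47; with gapmer 3, 6 rose, led by DDX60 at 1.66.

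Genes called the same way by both gapmers address which changes were seen with either oligonucleotide, though their sizes differed for some. DDX60 rose by 1.66 and 1.89 with gapmers 3 and 4, IFI44 by 1.52 and 2.94, and CGGBP1 by 1.48 and 1.40. TMEM171 rose by 1.36 and 1.91, the cell adhesion gene FLRT3 by 1.45 and 1.20, the lncRNA LINC00324 by 1.06 and 1.32, and IL1RN, the antagonist of interleukin 1, by 0.97 and 1.02. GPR89A (2.06 and 1.68; 0.94 with gapmer 4 as a mean over its probes), GPR89B (1.93 and 1.55), IFIT2 (1.20 and 3.47), IFIT1 (1.18 and 3.26) and HERC6 (0.95 and 2.75) complete the 12 largest shared rises as ranked by the smaller of the 2 changes, as the falls below also are. Among shared falls, PATJ read -1.34 and -2.32, the lncRNA LINC00052 -1.60 and -1.29, the atypical kinase MAPK4 -1.19 and -2.14 and the basement membrane gene NID2 -1.27 and -1.99. DMXL2 (-1.60 and -1.15), DENND4A (-1.57 and -0.88), RALGPS2 (-1.02 and -0.98) and CCDC91 (-0.93 and -0.78) also fell with both. So did the synaptic scaffold GPHN (-0.96 and -1.51), LRCH1 (-0.87 and -1.62), the motor MYO1C (-0.80 and -1.60) and the prolactin receptor PRLR (-0.92 and -0.88).

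In all, 405 genes were called the same way by both, 168 up and 237 down, which is 37.2% of gapmer 3 calls and 22.8% of gapmer 4 calls. Of these, 140 were also called different between the gapmers, among them IFIT2 and HERC6. A further 60 were called in opposite directions. Independent lists of these sizes would give 71 opposite calls, 24.7 shared rises and 50.6 shared falls, which leaves out the shared controls. The replicate block called 728 the same way, and without control replicate 3 the number was 238. Of the named genes, HERC6 lost its gapmer 3 call without control replicate 2 or 3 or gapmer 3 replicate 1 or 3 (adjusted p 0.0596 to 0.0799), and TMEM171 without control replicate 2 or 3 (0.0504 to 0.0525). IFIT1 lost its own without control replicate 1 or 3 or gapmer 3 replicate 1 or 3 (0.0757 to 0.0825). PRLR lost its gapmer 3 call without any 1 of 7 arrays, all but control replicate 1 and gapmer 3 replicate 2 (0.0536 to 0.137), and with array weights (-0.59, 0.103). It lost its gapmer 4 call without control replicate 2 or any 1 gapmer 4 array (0.0539 to 0.109).

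Across 13213 genes, which are not independent replicates, the log2 changes of the gapmers correlated at r = 0.346 (Spearman's rho 0.372). Because the same control arrays enter both changes, simulations with no true change gave r = 0.501 on average. Their arrays were drawn independently, without the pairing by replicate number seen in the values. The covariance was 0.0256 against 0.0063 in those simulations, an excess of 0.0193. The simulations gave 0 genes called the same way, which follows from holding no true change. Their top-ranked lists of the same sizes shared 383.8 genes on average and at most 416. Those genes were picked by rank, not called, and hold no true change. Their number therefore cannot say how many of the real 405 come from the shared controls. With 3 control arrays the group cannot be divided into parts of at least 2, so part of the overlap may come from the shared controls.

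**Figure D3:**
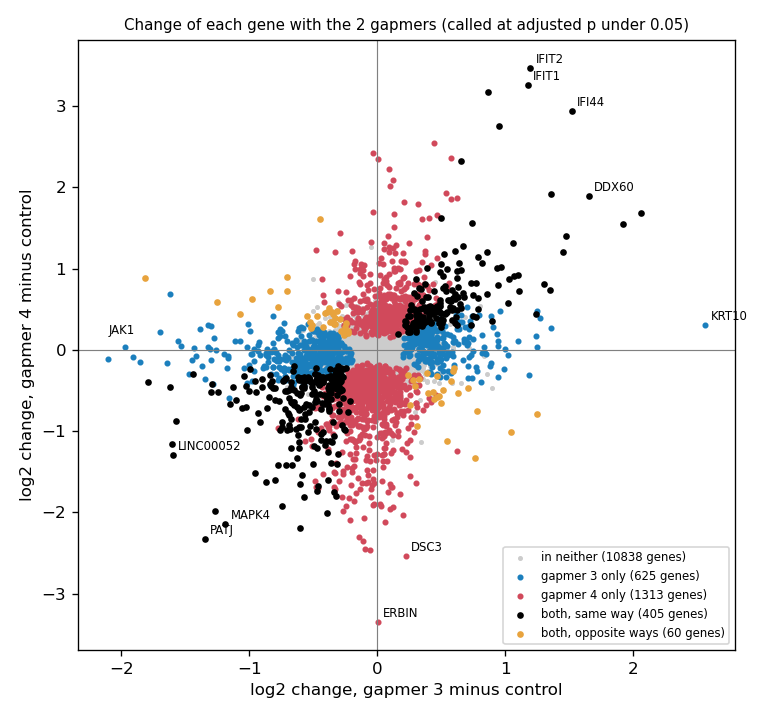
Log2 change from control with gapmer 3 (horizontal) and gapmer 4 (vertical), 1 point per gene, with genes called the same way by both picked out. IFI44 and DDX60 lie up on both axes, PATJ down on both, while JAK1, KRT10 and ERBIN lie along 1 axis.

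The mean of both gapmers against the control weighs them equally. GPR89A (1.87 ± 0.085), GPR89B (1.74 ± 0.072), CGGBP1 (1.44 ± 0.080) and IFIT2 (2.34 ± 0.183) rose, and PATJ (-1.83 ± 0.111), DENND4A (-1.22 ± 0.074) and LRCH1 (-1.25 ± 0.059) fell. In all, 1467 genes were called, 576 up and 891 down. The replicate block called 2320, and without control replicate 3 the number was 947. Of 35 lists, 4 were called at the preset correlation and 9 with the block. The 5 added were S phase genes (adjusted p = 0.106; 0.0041 with the block), fatty acid metabolism (0.0700; 0.0324), metallothioneins (0.1005; 0.0387), homologous recombination (0.1005; 0.0412) and ribosomal proteins (0.0819; 0.0492). All 5 were at adjusted p from 0.458 to 0.785 with an estimated correlation. Interferon response genes rose for 16 of 21 (19 adjusted over the list alone), with a mean change of 2.14-fold at adjusted p = 2.06e-18, and adjusted p = 0.287 with an estimated correlation. NF-kB and inflammatory genes rose for 4 of 16 (4 adjusted over the list alone): CXCL8 (0.90), PTGS2 (0.58), CCL20 (0.44) and the adhesion receptor ICAM1 (0.29). CCL20 lost its call without any 1 of 7 arrays, all but gapmer 3 replicate 1 and gapmer 4 replicate 1 (adjusted p 0.0555 to 0.198), and ICAM1 without control replicate 2 or 3 or gapmer 4 replicate 3 (0.0585 to 0.102). The list mean was 0.26 at adjusted p = 0.0012, and adjusted p = 0.246 with an estimated correlation. This rise lies with gapmer 4, since with gapmer 3 the list mean was -0.04 (adjusted p = 0.622), PTGS2 fell by 0.45, CCL20 read -0.33 (0.224), CXCL8 0.13 (0.695) and ICAM1 0.26 (0.0946; 0.0351 with the block). Mesenchymal genes rose for 6 of 16, led by VIM (1.06), TNC (0.83, but -0.03 with gapmer 3) and FN1 (0.70), with 6 up and 1 down adjusted over the list alone. TNC lost its call without control replicate 2 or 3, gapmer 3 replicate 1 or 2 or gapmer 4 replicate 3 (adjusted p 0.0503 to 0.141). Across the list the mean was 0.28 at adjusted p = 0.0026, and adjusted p = 0.246 with an estimated correlation. Cholesterol synthesis genes fell for 6 of 16 and rose for 1 (8 and 1 adjusted over the list alone), with SREBF2 at -0.47 and SQLE at -0.43. Their mean was -0.24 at adjusted p = 5.46e-04, and adjusted p = 0.584 with an estimated correlation. Lists called numbered 7 without control replicate 2, 9 without control replicate 3, 8 without gapmer 3 replicate 1 and 7 without gapmer 4 replicate 1.

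Gapmer 4 was compared directly with gapmer 3 to test where the oligonucleotides differed. XAF1, an interferon-induced pro-apoptotic gene, was higher with gapmer 4 by 2.46 ± 0.327 (adjusted p = 4.74e-04), the small GTPase ARL14 by 2.35 ± 0.238, IFIT3 by 2.31 ± 0.218, LINC00707 by 2.30 ± 0.204 and IFIT2 by 2.27 ± 0.211. JAK1 was higher with gapmer 4 by 2.00 ± 0.078 and TBP by 1.59 ± 0.120; with gapmer 4 these genes stood at 0.03 and 0.05 against the control. Lower with gapmer 4 were ERBIN by -3.36 ± 0.136, DSC3 by -2.77 ± 0.138, KDSR by -2.40 ± 0.096, MBNL1 by -2.36 ± 0.073 and KRT10 by -2.26 ± 0.093. PTGS2, which fell by 0.45 with gapmer 3 and rose with gapmer 4, differed by 2.05 ± 0.076. In all, 2106 genes differed, 1034 higher and 1072 lower with gapmer 4, and 140 of the 405 genes called the same way by both were among them.

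Lists called between the gapmers numbered 7 of 35, 5 higher and 2 lower with gapmer 4, and none held with an estimated correlation. Interferon response genes were higher for 18 of 21 (19 adjusted over the list alone), with a mean difference of 1.37 at adjusted p = 6.42e-17, and adjusted p = 0.203 with an estimated correlation. MAP kinase genes were higher for 13 of 19 (15 higher and 1 lower adjusted over the list alone), DUSP6 by 1.24, with a mean of 0.48 at adjusted p = 3.03e-07, and adjusted p = 0.203 with an estimated correlation. Part of that difference lies on the gapmer 3 side, where the mean was -0.12 (adjusted p = 0.0511; 0.0093 with the block), and adjusted p = 0.800 with an estimated correlation. NF-kB genes were higher for 8 of 16 (11 adjusted over the list alone), CXCL8 by 1.54 and CCL20 by 1.52, with a mean of 0.60 at adjusted p = 1.04e-05, and adjusted p = 0.171 with an estimated correlation. Fatty acid genes were lower for 9 of 20 and higher for 2 (10 and 2 adjusted over the list alone), ACSS2 by -1.27, with a mean of -0.24 at adjusted p = 8.91e-04, and adjusted p = 0.189 with an estimated correlation.

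Retinoic acid pathway genes were higher with gapmer 4 than with gapmer 3 for 3 of 7 (4 adjusted over the list alone): RDH10, a retinol dehydrogenase, by 0.69, RARRES1 by 0.60 and the nuclear receptor corepressor NRIP1 by 0.41. The mean was 0.34 at adjusted p = 0.0246, and adjusted p = 0.203 with an estimated correlation. Against the control the list was called with neither gapmer, with means of -0.16 (adjusted p = 0.594) with gapmer 3 and 0.18 (0.214) with gapmer 4. RARRES1 fell with gapmer 3 and read -0.38 with gapmer 4, called with the replicate block (adjusted p = 0.0288) but not in the main fit. Ribosome biogenesis genes were higher for 2 of 15 (2 adjusted over the list alone), NOP2 by 1.92 and ODC1, which makes polyamines rather than ribosomes, by 0.71. The mean was 0.27 at adjusted p = 0.0389, and adjusted p = 0.885 with an estimated correlation. Against the control the ribosome list was called with neither gapmer, at -0.17 (adjusted p = 0.146) with gapmer 3 and 0.10 (0.351) with gapmer 4. Basal and squamous genes were lower for 6 of 17 and higher for 1 (7 and 2 adjusted over the list alone), led by DSC3 and KRT10. KRT5 was lower by -1.06. The mean was -0.40 at adjusted p = 0.0389, and adjusted p = 0.662 with an estimated correlation. Against the control the basal list rose with gapmer 3 (mean 0.35, adjusted p = 0.0084, and 0.800 with an estimated correlation). With gapmer 4 it was not called (mean -0.05, median 0.08, adjusted p = 0.678). RDH10 lost its call without gapmer 3 replicate 2 or 3 (adjusted p 0.0555 to 0.0635). The ribosome list lost its call without gapmer 3 replicate 2 (adjusted p = 0.0767), gapmer 3 replicate 3 (0.158) or gapmer 4 replicate 1 (0.151). The basal list lost its own without control replicate 2 (0.0581), gapmer 3 replicate 3 (0.108), gapmer 4 replicate 2 (0.0756) or gapmer 4 replicate 3 (0.0547), and with no filter on dim probes (0.0582), and both were at 0.0510 after median centring. The ribosome list was also lost with a prior without trend (0.0506) and the stricter filter (0.0507). Without gapmer 4 replicate 1, the number of lists called was 11. The block called 8, adding genes of G2 and M phase with a mean of -0.09 (0.0786; 0.0414 with the block), and adjusted p = 0.885 with an estimated correlation.

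**Figure D4:**
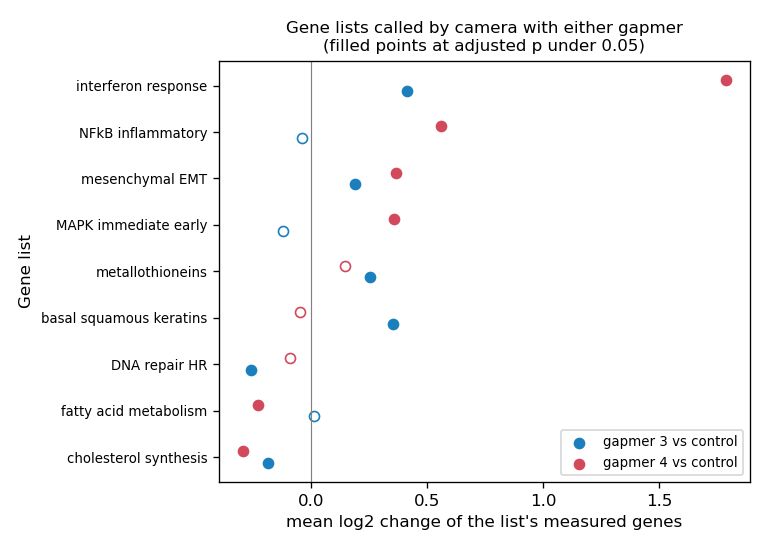
Mean log2 change from control of the measured members of each list called with either gapmer (horizontal), for gapmer 3 and gapmer 4; filled points were called and open points were not. The interferon list stands at 0.41 and 1.79, and the fatty acid list at 0.01 and -0.23.

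Calls among markers of other cell types stand beside 8.23% of all tested genes called with gapmer 3 and 13.4% with gapmer 4. Sets of 4 to 7 measured markers are too small to be set apart from these shares. Of 7 measured immune markers, the lysosomal glycoprotein CD68 rose with gapmer 4 by 0.46 ± 0.091. With gapmer 3 limma called 0 of the 7 (1 at an unadjusted p under 0.05), with CD68 at 0.32 (adjusted p = 0.0582; 0.0077 with the replicate block). Of 5 endothelial markers limma called 0 with either gapmer, 0 of them at an unadjusted p under 0.05. Of 4 fibroblast markers DCN, a matrix proteoglycan, rose by 1.25 ± 0.178 with gapmer 3. With gapmer 4 DCN read 0.47, called with the replicate block (adjusted p = 0.0079) but not in the main fit. Of 12 measured targets of p53, limma called 0 with either gapmer (3 and 2 at an unadjusted p under 0.05), with list means of 0.05 and 0.09 (adjusted p = 0.649 and 0.542). With the replicate block, 2 and 1 were called: among them TP53I3 stood at 0.38 with gapmer 3 (adjusted p = 0.0609; 0.0234 with the block) and AEN at 0.29 with gapmer 4 (0.0755; 0.0112 with the block). Cancer stem cell markers gave 1 fall of 11 with gapmer 3, MYC by 0.32 ± 0.068, and with gapmer 4 CD24 fell by 0.68 ± 0.090 while CD44 rose by 0.38 ± 0.050. With gapmer 3 that list's mean was 0.03, its median -0.02 and its test pointed down (adjusted p = 0.984). With gapmer 4 (adjusted p = 0.351) its mean was 0.08. MYC lost its call without control replicate 2 or 3 or gapmer 3 replicate 1 or 3 (adjusted p 0.0519 to 0.0772).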

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

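In this part, the test of a deeper loss of NRAD1 with gapmer 4 was chosen only after the result it measures was seen.

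The direct test between the gapmers found 2106 genes whose changes differed. The gapmers called 60 genes in opposite directions, against 71 expected of independent lists. That figure leaves out the shared controls, which push both changes the same way, so it cannot say whether 60 is few or many. By list, the mean difference between gapmer 4 and gapmer 3 was 1.37 for interferon response genes, 0.60 for NF-kB and inflammatory genes, 0.48 for MAP kinase genes, 0.34 for retinoic acid genes and 0.27 for ribosome biogenesis genes. It was -0.24 for fatty acid genes and -0.40 for basal and squamous genes. Among 24805 tested probes with no gene name here, which no comparison above uses, 439 (1.77%) changed with gapmer 3 and 801 (3.23%) with gapmer 4.

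Of 21 interferon response genes, 6 rose with gapmer 3 and 20 with gapmer 4, and the list was higher with gapmer 4 by 1.37 on average, with adjusted p = 0.800, 0.170 and 0.203 with an estimated correlation for gapmer 3, gapmer 4 and their difference. Leaving out any 1 array kept at least 0.886 of the list mean, which argues against a single array as the whole source. Rescaling the arrays kept at least 0.985 of it. The deposited array medians already lay between 5.30 and 5.37, so rescaling could change the mean little. Scale differences left between the deposited arrays are thus too small to give these means, and the authors' own normalization was not tested. A deeper loss of NRAD1 with gapmer 4 stays undecided: the probe read 0.11 ± 0.146 higher with gapmer 4 than with gapmer 3, or 0.76 standard errors, on 1 dim probe (32.5th percentile of brightness) whose change passed the test with neither gapmer. An effect of losing NRAD1 stays open and untested, as does a response to the oligonucleotides themselves, since the design holds 1 control gapmer. JAK1, a kinase of interferon receptors, fell with gapmer 3 and stood near the control level with gapmer 4. Whether that fall lowered the interferon genes with gapmer 3 was not tested.

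Of the genes that fell at least 2-fold, 54 of 60 with gapmer 3 and 167 of 170 with gapmer 4 differed between gapmers, while 21 and 43 also fell with the other gapmer. The median change with the other gapmer was 0.134 and 0.122 of their own, which argues against a loss shared by both gapmers as the source of these sets as a whole, not for those 21 and 43. The genes that fell were longer than those that rose, with ratios of median gene length of 3.50 (95% bootstrap interval 1.57 to 8.49) and 4.88 (2.93 to 8.16). Probe brightness does not account for this, since in pairs matched on brightness the ratios were 6.42 (1.89 to 12.6) and 4.55 (2.93 to 8.70). Uncalled genes with a high p and matched brightness served as a second reference. Against them the ratios were 4.53 (2.32 to 8.42) and 5.30 (3.76 to 7.28) for genes that fell. For genes that rose they were 1.33 (0.44 to 3.18) and 1.54 (0.76 to 2.63), so the falls were long rather than the rises short. A candidate explanation, as a hypothesis only, is that each gapmer also binds partial matches in long primary transcripts; no sequence was searched, and other causes that act on long genes stay open and untested.

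The 6 arrays of each comparison between groups of 3 make 10 splits, too few for a share under 0.05. The real split called 1090 genes with gapmer 3, 1778 with gapmer 4 and 2106 between the gapmers, and the highest of the other splits called 0 in each, so 1 of 10 splits reached the real count. Each of these has 3 other splits that part as many same-number pairs, with 0 genes called; the other 6 part 1 pair. For lists, 3, 4 and 3 of the 10 splits called as many as the real 6, 6 and 7, with highest other values of 11, 12 and 8. Among the splits that part as many pairs, the highest other values were 1, 3 and 4. Of 100 drawn regroupings of the 9 arrays, out of 840 possible, only the real one called as many as 1467 genes for the mean of both gapmers (highest other 501; 144 in the 11 that part as many pairs) or 405 genes the same way (highest other 223; 0 in those 11). Among regroupings drawn without regard to the pairs, these counts argue against a chance arrangement of the arrays as a whole. Regrouping arrays that truly differ raises the spread within groups, so the low counts do not estimate false calls. The 11 others that part as many pairs are too few for a share under 0.05. For the 4 lists called with the mean of both gapmers chance cannot be excluded, since 78 of the 100 regroupings called as many, with up to 12 (6 in those 11).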

How the results depend on the processing

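In this part, the fits without the 3 arrays numbered 1 and with only genes with at most 2 arrays at one value were chosen only after the data were seen.

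No result reversed under the settings run for it. A named gene could count as reversed only if it was called in the main fit or in the alternative. Counts, lists and single genes were not all run under each of the 21 settings. Of 13517 checks of 764 changes of named genes, 12791 stayed on their side of the threshold, 445 lost a call and 281 gained one, and 89 changes lost a call at least once. Besides leaving out an array, the settings that ended calls of named genes were only the 6 arrays compared (23), a prior without trend (20), median centring (8), no filter (6), quantile normalization (5), array weights (2) and a mean over probes (1). For the 23 list calls, 400 of 455 checks kept the call and 55 lost it; in 23 of those the setting was an estimated correlation in place of the preset 0.01, which leaves 0 lists in each of the 4 comparisons (unadjusted p under 0.05: 1 with gapmer 3, 4 with gapmer 4, 3 for the mean, 5 between gapmers). A larger correlation does not account for all 23, since the estimate was under 0.01 for mesenchymal genes (-0.009) and retinoic acid genes (-0.121). By construction, this setting also lowers the degrees of freedom of the test to the 6 residual ones; the share of each was not tested. The fry test called 3, 12, 5 and 11 lists. With gapmer 3 it did not call the interferon, cholesterol or repair lists (fry adjusted p = 0.258 each) or metallothioneins (0.0943). With gapmer 4 it called the interferon list (3.84e-04). Its mixed p called 26, 27, 27 and 27 of the 35 lists, so changed members were not particular to the lists described. Other settings that moved list counts were the stricter filter on dim probes (3 with gapmer 3) and leaving out the 3 arrays numbered 1 (10 with gapmer 3), and the replicate block gave 9 for the mean; for these the cause was not tested. Without the 3 arrays numbered 1, all 23 lists kept their call, and 993 genes were called with gapmer 3, 1771 with gapmer 4, 1413 for the mean, 1924 between gapmers and 393 the same way. Among the 9990 genes with at most 2 arrays at one value, the counts were 1172, 1849, 1558, 2173 and 442. The block ended no call of these lists or of a named gene. It added list calls, for totals of 9 with gapmer 3, 7 with gapmer 4, 9 for the mean and 8 between gapmers, and 93 calls among the changes of named genes.

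Counts of genes fell by construction where a fold minimum was added to the adjusted p. At least 1.5-fold left 376 genes with gapmer 3, 702 with gapmer 4, 384 for the mean, 794 between gapmers and 99 called the same way by both. Unadjusted p under 0.05 with at least 2-fold, which changes both the p and the fold limit, gave 90, 253, 79, 268 and 15. Array weights, which ranged from 0.550 for gapmer 3 replicate 1 to 2.48 for control replicate 3, called 1891 genes with gapmer 3, 2282 for the mean and 698 the same way. The replicate block called 1801, 2320 and 728. The cause was not tested for these. Median centring raised the share of falls among called genes from 61.1% to 63.6% with gapmer 3, 56.6% to 63.5% with gapmer 4, 60.7% to 65.8% for the mean and 50.9% to 56.3% between gapmers, so these shares depend on scaling.

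Leaving out each array in turn gave 677 to 1123 genes with gapmer 3 (lowest without control replicate 3, and 719 without gapmer 3 replicate 2), 1291 to 1780 with gapmer 4, 1515 to 2172 between gapmers, 947 to 1374 for the mean (lowest without control replicate 3) and 238 to 390 the same way (lowest without control replicate 3). Lists ranged from 4 to 9 with gapmer 3 (9 without gapmer 3 replicate 1, 4 without gapmer 3 replicate 2), 6 to 8 with gapmer 4, 5 to 11 between gapmers (11 without gapmer 4 replicate 1) and 4 to 9 for the mean (7 without control replicate 2, 9 without control replicate 3, 8 without gapmer 3 replicate 1, 7 without gapmer 4 replicate 1). The correlation across genes ranged from 0.317 to 0.400. NRAD1 stayed uncalled, from -0.45 to -0.20 with gapmer 3 (adjusted p 0.170 to 0.524) and -0.33 to -0.09 with gapmer 4 (0.265 to 0.771), and at -0.18 and -0.15 with array weights; the stricter filter removes its probe and gives no value. Its mean signal of 4.48 lies near the limit of 4.04 below which probes were left out as dim.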

Other observations

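Sensors of foreign nucleic acids gave 4 rises of 14 measured with gapmer 4 and a list test that missed the threshold (adjusted p = 0.0799). TLR3, which senses double-stranded RNA in endosomes, rose by 1.20 ± 0.096, the antibody receptor TRIM21 by 0.81 ± 0.129, the adaptor MYD88 by 0.63 ± 0.078 and STING1, the adaptor of cytosolic DNA sensing, by 0.52 ± 0.101. STING1 also rose with gapmer 3, by 0.42 ± 0.101, a call lost without control replicate 1 or 3 or gapmer 3 replicate 1 or 2 (adjusted p 0.0559 to 0.0853). Of 14 regulators of apoptosis, PMAIP1, a BH3-only activator, rose by 1.86 ± 0.176 and MCL1, which blocks apoptosis, by 0.41 ± 0.064 with gapmer 4, while BID, another BH3-only gene, fell by 0.49 ± 0.107; the list was not called (adjusted p = 0.351). JAG1, a ligand of Notch receptors, rose by 1.32 ± 0.090 with gapmer 4, and the list of Notch and Wnt targets was not called (adjusted p = 0.289).

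Targets and partners of YAP gave 0 rises and 4 falls of 12 with gapmer 3, and 3 rises and 3 falls with gapmer 4, and the list was called in neither (adjusted p = 0.126 and 0.6). TEAD1 fell by 0.47 ± 0.083 and 1.74 ± 0.083, while ANKRD1 rose by 0.60 ± 0.123 with gapmer 4. S phase genes gave 2 falls of 31 with gapmer 3, UHRF1 and NASP, and 3 with gapmer 4. The replicate block called 5 and 10 of them. The list's adjusted p was 0.398 and 0.0916. The latter was 0.0074 with the block, and adjusted p = 0.856 with an estimated correlation. NASP lost its gapmer 3 call without control replicate 1 or 2 or gapmer 3 replicate 2 or 3 (adjusted p 0.0725 to 0.117). Hypoxia genes were not called as a list (adjusted p = 0.252 and 0.272), but with both gapmers BNIP3, a mitophagy receptor, fell by 0.56 and 0.80 and ANKRD37 rose by 0.53 and 0.79. The lysosomal protease CTSL rose by 0.50 and 0.46. The lysosomal membrane gene LAMP1 fell by 0.81 ± 0.098 with gapmer 4, and the list of lysosome and autophagy genes was called with neither (adjusted p = 0.398 and 0.968). The heat-shock genes HSPA1A and HSPA1B, which are near-identical paralogs, fell by 0.67 and 0.62 with gapmer 4, while HSPA4L rose by 0.54 ± 0.074. Heat-shock genes gave 1 rise and 3 falls of 10 there, and the list was not called (adjusted p = 0.351).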
